A study of Mus musculus with 6 samples.

How the data were processed

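Poly-A RNA of epididymal white adipose tissue, the fat pad attached to the epididymis of male mice, was sequenced as direct cDNA on an Oxford Nanopore device, which reads cDNA molecules from end to end without PCR amplification. Per the labels' protocols, male C57BL/6N mice of 20 weeks, an inbred strain, were the source, and 100 ng of poly-A RNA went into each library. Per the labels, 3 mice were controls (ctrl; mice 5, 6 and 10) and 3 were exposed to cold (mice 7, 12 and 16), housed alone at 4 °C for 24 h before harvest. The base housing was at 22 to 24 °C, and the labels do not say whether control mice were housed alone. Each library is named here by its group and mouse number, so replicates are separate animals.

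The authors deposited raw read counts per annotated transcript, 2 files for each mouse (X1 and X2), 12 in all. Only transcripts with at least 1 read are listed, and all values are whole numbers. Reads were aligned with minimap2, a long-read aligner, to GRCm38, per the submitters' processing notes, which give no version. The counting tool, its treatment of reads that match several transcripts and its use of strand are not given in the sources used here. Reads from overlapping genes, and from genes with near-identical copies, may therefore be split between them by rules that are unknown.

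What separates the 2 files of a mouse is not stated. Over the transcripts with at least 20 reads in both files together, the chi-square statistic of their counts per degree of freedom lay between 1.02 and 1.06 in the 6 mice, so they differed by about the sampling noise. Neither file contained the other. Both were summed and counted as 1 sample, which leaves 3 samples per group. Across genes, log2 CPM (counts scaled by the reads of the library) of the 2 files of a mouse had a Pearson r of 0.921 to 0.959. Genes are not independent replicates in these correlations.

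Of 61729 transcript identifiers, 61434 were found with the same version in the GENCODE M21 annotation of GRCm38 and 61538 when the version was ignored. The unmatched 191 held 0.139% to 0.165% of the reads of a library and entered only the transcript tests. Transcript counts were summed to 23492 genes. Gene names, types and positions are those of GENCODE M21, 1-based on GRCm38.

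Total reads per mouse were between 726283 and 1341592. In the library with the fewest reads, 1 read is worth 1.38 CPM and the limit that a count of 0 allows, 3 reads, is 4.14 CPM. In the deepest library these are 0.747 and 2.24 CPM. CPM values of genes are relative to the reads assigned to genes and those of transcripts to all reads, and floors and intervals cover counting error only.

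Genes and transcripts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test after TMM normalization and filterByExpr with its defaults (minimum count 10), with Benjamini-Hochberg adjustment and a threshold of 0.05. Unless another tool is named, adjusted p stands for this test over all genes or transcripts tested. Log2 fold changes are cold minus ctrl, with the standard error (SE) derived from the F statistic. Transcript usage, the share of a gene's reads that each of its transcripts takes, was tested with diffSpliceDGE of edgeR and the Simes p per gene. The 36 gene lists (20 pathways and 16 cell types) were tested with camera of limma 3.58.1 with a preset correlation of 0.01 where at least 5 members passed the filter, which held for 29. Lists were also tested with an estimated correlation and with fry. Sums of CPM over the members of a list were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 samples is 0.1.

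The lists, tests and alternatives and the rule for named genes were fixed before the data were examined. Named are the 12 genes with the largest rise and the 12 with the largest fall, or all if fewer, among those past the threshold with a mean of at least 10 reads in the higher group and no overlap between groups. To these come up to 4 members with the smallest p from each of the 29 lists tested, all of which are described, and in any case Ucp1, Adipoq, Lep, Fasn, Pnpla2, Lipe and Ppargc1a. For transcripts the rule takes the 8 with the smallest p in each direction whose gene does not pass, and for usage the 8 genes with the smallest p. Other genes named were chosen after their values were seen, and the text says so. A few genes and transcripts that the rule takes are not reported here.

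The tests were checked on simulated counts drawn from the means, library sizes and dispersion trend of these libraries. Each gene or transcript took the dispersion of the trend at its mean. The check therefore does not cover genes that vary more between mice than the trend. Of 200 genes changed among 9786 tested, those changed 2-fold were called in 77.3% of cases and those changed 4-fold in 96.9%, and 6.08% of calls were false. For transcripts (12278 tested) the shares were 60.2% and 98.9%, with 5.84% false calls. Of genes with 1 transcript changed 4-fold, 86.5% were called in the usage test over 2628 genes, with 1.19% false calls. Of 40 random lists over 9772 genes, all 4 with members raised 1.5-fold were called by camera, with 0 false calls. Genes were drawn independently there, so this check does not cover lists whose genes vary together. The mitochondrially encoded mRNAs, for example, had an estimated correlation of 0.584.

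Alternatives were DESeq2 1.42.0 size factors, no composition factor, the DESeq2 and limma-voom tests, no filter, a filter of 10 reads in 3 libraries, either file of a mouse alone, each mouse left out in turn, and mitochondrially encoded genes left out. A fit without cold 7 and cold 12 was added after seeing the data, because these libraries held sperm transcripts. The 7 lists with too few tested members were not tested with camera and are given as sums of CPM, but some had enough members in an alternative and count there (T and NK cells with no filter, testis germ cells with no filter or with a mouse left out). Genes under the filter were not tested.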

Results

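Full-length cDNA of epididymal white adipose tissue was counted per transcript in 3 control mice and 3 mice kept at 4 °C for 24 h. The comparison asks which genes, transcripts and transcript choices of this fat depot differ after a day in the cold. Total reads were 939107 in ctrl 5, 1341592 in ctrl 6 and 1134875 in ctrl 10. The cold libraries held 726283 (cold 7), 1194134 (cold 12) and 784035 (cold 16) reads. Between 16905 and 18252 genes were seen per library. On TMM-normalized log2 CPM of the tested genes, control mice correlated across genes at r = 0.962 to 0.963 with each other, cold mice at 0.931 to 0.953, and mice of different groups at 0.935 to 0.953.

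In the cold, 64 of 9772 tested genes passed the threshold, 53 higher and 11 lower. The largest rises were in genes nearly without reads in the controls. Pdzk1ip1 (ENSMUSG00000028716.15, chromosome 4, 115088708 to 115093899), a small membrane protein that binds PDZ domains, had 0 reads in all control libraries and 17.6 ± 5.77 CPM (SD, n = 3) in the cold. It was at least 20.6-fold higher, against a floor of 3 reads over the control group (edgeR adjusted p = 9.73e-05). Calml3, a calmodulin-like protein, went from 1.42 ± 2.46 to 46.7 ± 27.8 CPM (SD, n = 3, edgeR adjusted p = 8.82e-05). Ppp1r1b, an inhibitor of protein phosphatase 1, was 37.9-fold higher by its 3 reads in controls and 90 in the cold, with a 95% counting interval of 12.6 to 187. Plet1, a surface protein of epithelia, was 32.4-fold higher by 3 and 77 reads, with an interval of 10.7 to 161.

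Mmp7 (ENSMUSG00000018623.9, chromosome 9, 7692090 to 7699585), the secreted protease matrilysin, rose by 4.99 ± 0.58 (SE) on the log2 scale, from 2.99 to 82.5 CPM (edgeR adjusted p = 6.92e-05). Cuzd1 (ENSMUSG00000040205.8, chromosome 7, 131308554 to 131322292), a CUB and zona pellucida domain protein, had the smallest adjusted p (3.26e-05, edgeR) and rose by 4.26 ± 0.42 (SE). Epcam, an adhesion molecule of epithelial cells, rose by 4.65 ± 0.65, and Cldn7, a tight junction protein, by 3.89 ± 0.61. Mt3, a metallothionein, rose by 4.52 ± 0.56, the coiled-coil gene Ccdc153 by 4.17 ± 0.57, the acyl-CoA synthetase gene Acsbg1 by 4.17 ± 0.52 and Dcdc2a, a doublecortin domain protein, by 3.87 ± 0.55. In 11 of these 12 genes the call held without any 1 mouse, and Cldn7 lost it without cold 12 (edgeR adjusted p = 0.0821). Calml3, Epcam, Ccdc153 and Dcdc2a lost it by DESeq2 (adjusted p up to 0.245), and Mt3 and Dcdc2a by limma-voom. The size of some rises depended on single mice. With each mouse left out, the log2 fold change was 3.97 to 8.06 for Epcam and 4.59 to 8.67 for Calml3. It was 4.32 to 6.55 for Mmp7 and 3.61 to 6.22 for Ccdc153. Most control reads of these genes were in ctrl 5.

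Of the 53 higher genes, 28 rose at least 4-fold by the fitted fold change and 9 were not protein-coding. In 44 of them cold 7 was the lowest of the cold libraries. Among genes chosen after their values were seen, Lrp2, an endocytic receptor of absorptive epithelia, rose from 11.1 ± 5.19 to 87.6 ± 46.1 CPM (SD, n = 3). The pump subunit gene Atp1b1 rose from 24.5 ± 12.1 to 119 ± 38.4 CPM, and the non-coding gene Gm26880 from 47.1 ± 12.1 to 232 ± 122 CPM. Of the 64 genes, 14 overlap another annotated gene with at least 10 reads, among them Cuzd1 (Fgfr2), Podn (Scp2), Gas6 (Tmem255b) and Hdgfl2 (Plin4), so their reads are uncertain.

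The 11 lower genes fell by less than the leading risers rose. Sult1e1 (ENSMUSG00000029272.8, chromosome 5, 87575969 to 87591594), the estrogen sulfotransferase, fell from 82.5 ± 1.57 to 30.3 ± 10.1 CPM (SD, n = 3, edgeR adjusted p = 0.00097). Podn (ENSMUSG00000028600.15, chromosome 4, 108014791 to 108096445), a small leucine-rich matrix proteoglycan, fell from 199 ± 23.9 to 101 ± 4.54 CPM (edgeR adjusted p = 0.00097). Rprml fell by 1.36 ± 0.25 (SE, log2 scale), the collagen gene Col6a6 by 1.08 ± 0.24 and Gadd45g, a stress-induced gene, by 0.98 ± 0.21. Gas6, a ligand of TAM receptor kinases, fell by 0.74 ± 0.15, the membrane protein gene Emp1 by 0.74 ± 0.14 and Dhrs3, a retinaldehyde reductase, by 0.73 ± 0.17. Cd200, a surface glycoprotein, fell by 0.68 ± 0.15 and Hdgfl2 by 0.67 ± 0.14. Only Sult1e1 and Podn of the 11 kept the call without each of the 6 mice in turn.

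**Figure D1:**
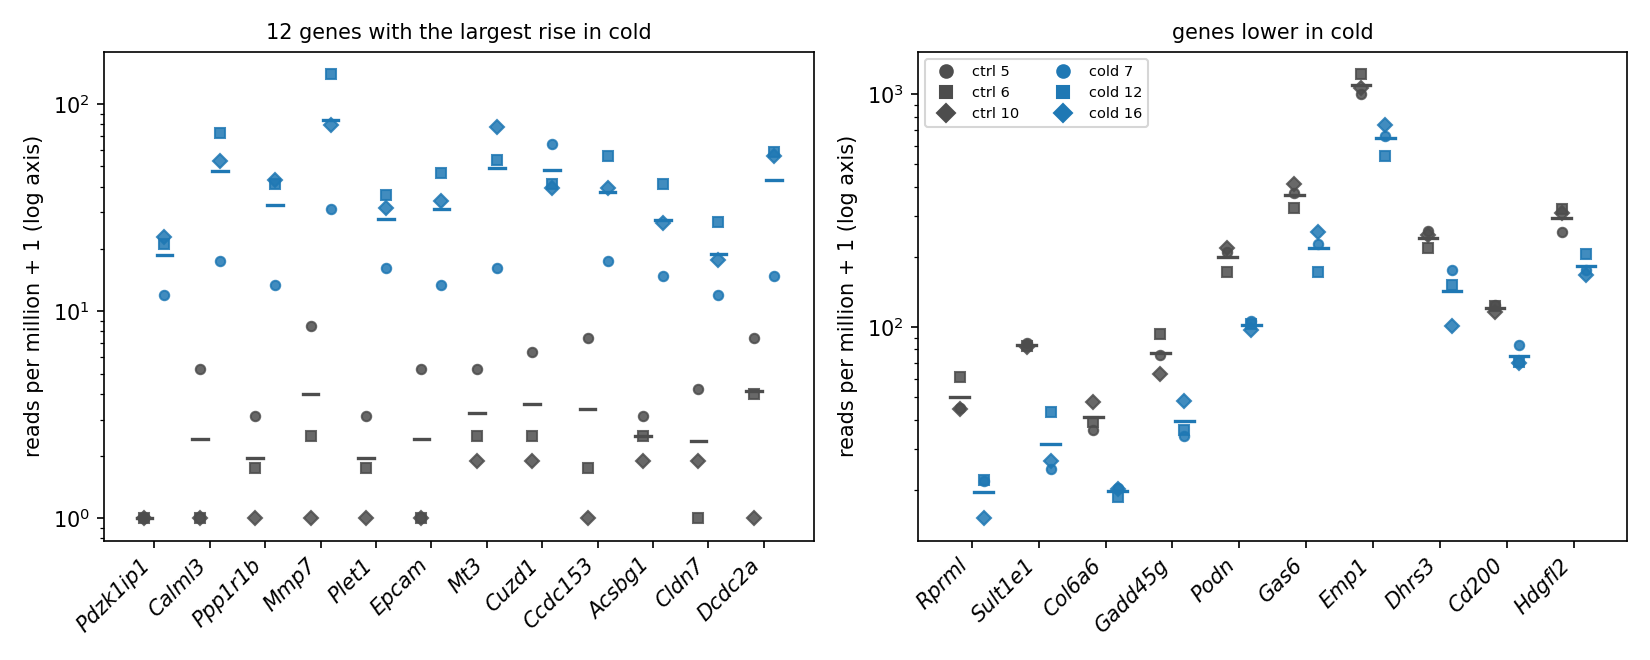
CPM plus 1, on a log axis, of the 12 genes with the largest rise (left) and of lower genes (right); each point is a mouse, grey for ctrl and blue for cold, and each bar is the mean of 3 mice. The cold mice lie above all control mice in each gene on the left and below all of them in each gene on the right, and Pdzk1ip1 has 0 reads in every control mouse.

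The number of called genes depended on the mice. It was 199 without cold 7, 106 without ctrl 5, 35 without cold 12 and 141 without both cold 7 and cold 12, a fit added after seeing the data. Groups did not overlap in 1334 genes, 13.7% of those tested, where chance gives 10%.

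Pnpla2 (ENSMUSG00000025509.15, chromosome 7, 141455198 to 141460743), the adipose triglyceride lipase that starts lipolysis, rose from 1243 ± 90 to 1912 ± 91.8 CPM (SD, n = 3), by 0.65 ± 0.12 (SE) on the log2 scale (edgeR adjusted p = 0.00971). Thrsp (ENSMUSG00000035686.8, chromosome 7, 97412938 to 97417730), a nuclear protein tied to lipid synthesis, rose from 1036 ± 79.8 to 1635 ± 269 CPM (edgeR adjusted p = 0.013). Ckb, the brain-type creatine kinase, rose from 71.5 ± 11 to 136 ± 54.4 CPM (edgeR adjusted p = 0.0355), with overlap between cold 7 and the controls. Without cold 12 the adjusted p was between 0.0663 and 0.445 for the named genes that lost the call, Pnpla2, Thrsp and Ckb among them. The same 3 genes lost it without ctrl 6 (edgeR adjusted p 0.0506 to 0.155 over the genes that did), Thrsp and Ckb without ctrl 10, and Ckb without cold 16, where the adjusted p of lost calls was 0.0634 to 0.162 and 0.0504 to 0.139 (edgeR).

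Among the 26 tested genes of lipolysis and the lipid droplet, 1 rose, 0 fell and 25 did not pass (5 with p adjusted over the list alone, 4 higher and 1 lower). The acyl-CoA synthetase gene Acsl1 had 1041 ± 182 CPM in controls and 1555 ± 274 in the cold (SD, n = 3, edgeR adjusted p = 0.0908). Adrb3, the β3-adrenergic receptor of adipocytes, had 963 ± 282 and 600 ± 135 CPM (edgeR adjusted p = 0.178), and the adenosine receptor gene Adora1 had 100 ± 24.5 and 138 ± 6.69 CPM. Lipe, the hormone-sensitive lipase, had 1304 ± 35.4 and 1205 ± 97.1 CPM (edgeR adjusted p = 0.919). Of 25 genes of lipogenesis, Thrsp rose and 24 did not pass (2 higher adjusted over the list alone). Fads2, a fatty acid desaturase, had 17.8 ± 4.91 and 33.8 ± 6.63 CPM, Mid1ip1 43.4 ± 5.93 and 64.9 ± 20.7 CPM, and Acacb 48 ± 10.3 and 72.4 ± 19.7 CPM. Fasn, the fatty acid synthase, had 903 ± 241 and 928 ± 552 CPM (edgeR adjusted p = 0.976), with the cold value set by cold 16: without it the log2 fold change was -0.52.

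Triglyceride synthesis had 0 of 17 tested genes past the threshold and 1 adjusted over the list alone, the glycerol kinase gene Gk at 5.8 ± 2.04 and 14.7 ± 3.34 CPM (edgeR adjusted p = 0.179). The glycerol phosphate dehydrogenase gene Gpd1 had 406 ± 24.9 and 560 ± 181 CPM, Pck1 1206 ± 222 and 928 ± 135 CPM, and Gpat3 139 ± 16.2 and 109 ± 29.4 CPM. Fatty acid uptake had 0 of 18 past the threshold and 6 adjusted over the list alone, 4 higher and 2 lower. The transporter gene Slc27a1 had 276 ± 26.2 and 389 ± 43 CPM, the caveola gene Cav1 3104 ± 171 and 2228 ± 352 CPM, and Fabp5 178 ± 23.7 and 235 ± 17.3 CPM.

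Ucp1, the uncoupling protein of brown and beige adipocytes, had 1 read over the control group and 1 over the cold group, with 95% Poisson upper bounds of 1.63 and 2.06 CPM. Ppargc1a, a coactivator of mitochondrial biogenesis, had 10 reads over the controls and 17 over the cold mice. Both had too few reads to pass the filter and were not tested. Of the 25 thermogenic and beige genes 8 were tested and 0 passed, with 1 higher (Gk) and 1 lower (Adrb3) adjusted over the list alone. Cox8b, a muscle and brown fat isoform of a cytochrome oxidase subunit, had 28.5 ± 11.6 and 45.1 ± 20.2 CPM, and Ucp3 19.2 ± 0.96 and 28.6 ± 7.87 CPM.

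**Figure D2:**
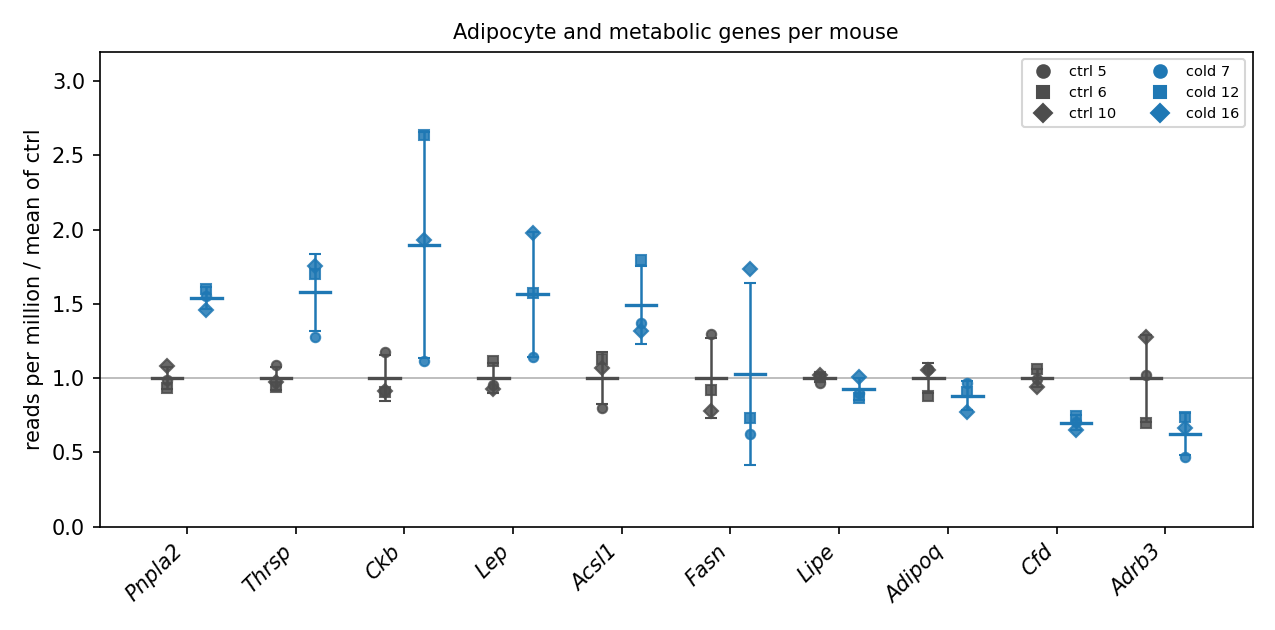
CPM divided by the mean of the control mice, for 10 genes of adipocytes and metabolism; points are mice (grey ctrl, blue cold), bars are the mean and SD of 3 mice. Pnpla2 and Thrsp are higher in each cold mouse than in any control mouse, Cfd is lower in each, and the cold mice are far apart in Fasn and Ckb.

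Of 22 tested adipokines and secreted factors, Lcn2 rose, 1 fell and 20 did not pass (2 higher and 2 lower adjusted over the list alone). Lcn2 (ENSMUSG00000026822.14, chromosome 2, 32384633 to 32388252), the iron-siderophore carrier lipocalin 2, rose from 13.3 ± 6.98 to 97 ± 45.8 CPM (SD, n = 3, edgeR adjusted p = 6.92e-05). Lep, the hormone leptin, had 437 ± 44.4 and 685 ± 184 CPM (edgeR adjusted p = 0.0628), and passed in 5 alternatives. Cfd, the secreted protease adipsin, had 15536 ± 914 and 10879 ± 760 CPM (edgeR adjusted p = 0.0857), and passed in 5 alternatives, DESeq2 and limma-voom among them. Adipoq, adiponectin, had 3449 ± 351 and 3039 ± 338 CPM (edgeR adjusted p = 0.843). The 20 markers of mature adipocytes had a median log2 fold change of -0.08, with 1 higher (Pnpla2), 0 lower and 19 not past the threshold, and 2 higher and 2 lower adjusted over the list alone.

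In the immediate early and cAMP-induced list, Gadd45g fell and 22 of 23 tested genes did not pass, with 1 lower adjusted over the list alone. Klf4 had 78.7 ± 22.6 and 57.3 ± 5.3 CPM, Dusp1 65.8 ± 29.3 and 46.2 ± 3.74 CPM, and Gadd45b 10.4 ± 2.89 and 15.3 ± 2.24 CPM. Of 21 glucocorticoid-responsive genes Lcn2 rose and 20 did not pass, with 2 higher adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a had 17 ± 7.12 and 35.5 ± 10 CPM, the metallothionein gene Mt1 426 ± 77.7 and 564 ± 26.1 CPM, and Cebpd 43.7 ± 5.58 and 32.6 ± 4.39 CPM.

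By camera, 3 of 29 lists passed the threshold, all upward, but 0 passed with an estimated correlation between genes or by fry, and 6 of the 10 splits of the mice, the real one included, gave at least 3. Mitochondrially encoded mRNAs, which specify subunits of the respiratory chain and ATP synthase, were higher in 13 of 13 genes with a median of 0.33 on the log2 scale (camera adjusted p = 0.00071), although 0 of the 13 passed alone and the list did not pass with an estimated correlation (camera adjusted p = 0.811) or by fry (adjusted p = 0.42). Adjusted over the list alone 1 was higher, mt-Atp8, at 103 ± 4.91 and 164 ± 64.6 CPM (SD, n = 3); its reading frame overlaps mt-Atp6. mt-Co2 had 5418 ± 116 and 6783 ± 670 CPM, mt-Cytb 7674 ± 538 and 9550 ± 1295 CPM, and mt-Nd2 2701 ± 52.4 and 3478 ± 900 CPM. Without cold 16 the median of the 13 genes was 0.17 and the camera adjusted p 0.0568. Cold 16 also stood apart in read types, with 86.9% of reads on protein-coding transcripts and 4.38% on retained introns, against 89.3% to 89.7% and 3.25% to 3.63% in the other 5 libraries. Reads on mitochondrial tRNAs were 0.275% in cold 16 and 0.117% to 0.147% elsewhere.

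Cytosolic ribosomal protein mRNAs were higher in 42 of 46 genes with a median of 0.11 (camera adjusted p = 0.0249, and 0.866 with an estimated correlation), 0 past the threshold alone or adjusted over the list alone. The list did not pass without ctrl 5, ctrl 6, cold 7 or cold 12 (camera adjusted p 0.199, 0.159, 0.267 and 0.187), with no filter (0.292) or with X2 files (0.0914). Rps14 had 703 ± 66.4 and 824 ± 32.5 CPM, Rpl38 744 ± 105 and 895 ± 143 CPM, Rpl27 557 ± 49.1 and 649 ± 12.2 CPM and Rpl8 462 ± 26.5 and 534 ± 11.2 CPM. These genes have many processed pseudogenes that could share their reads. The list of creatine, calcium and other futile cycles had a median of 0.39 over 7 tested genes (camera adjusted p = 0.0249, and 0.811 with an estimated correlation). It did not pass without ctrl 5, cold 7 or cold 16 (camera adjusted p 0.199, 0.166 and 0.101), with a filter of 10 reads in 3 libraries (0.0899), with no filter (0.143) or with X1 files (0.101). Its Ckb rose, and 3 genes were higher adjusted over the list alone, Ckb, Gk and the calcium pump gene Atp2a2 (74.8 ± 6.57 and 101 ± 5.79 CPM); the creatine transporter gene Slc6a8 had 17.1 ± 9.23 and 23.6 ± 4.41 CPM. By the mixed test of fry, which ignores direction, 5 lists passed. They were lipolysis and lipid droplet (fry mixed adjusted p = 2.11e-05), mature adipocyte (0.00128), fatty acid uptake (0.0115), mesothelial (0.0115) and futile cycles (0.0226). In the lipolysis, mature adipocyte and uptake lists, members passed in both directions adjusted over the list alone, while the medians were -0.02, -0.08 and 0.02. In the mesothelial and futile cycle lists, with medians of -0.16 and 0.39, only higher members passed that way.

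The oxidation lists held no gene past the threshold. Of 24 tested genes of fatty acid beta-oxidation 13 were higher and 11 lower, with 0 past it over all genes or over the list alone. The carnitine palmitoyltransferase gene Cpt2 had 85.6 ± 5.14 and 107 ± 11.7 CPM (SD, n = 3), the enoyl-CoA hydratase gene Echs1 270 ± 15.9 and 219 ± 30.6 CPM, and Acads 105 ± 6.42 and 89.2 ± 6.83 CPM. Nuclear genes of oxidative phosphorylation had a median log2 fold change of 0.07 over 41 genes (camera adjusted p = 0.186), and 0 passed. Cytochrome c (Cycs) had 305 ± 44.2 and 390 ± 50.3 CPM, Atp5g1 170 ± 6.57 and 208 ± 7.15 CPM, Ndufb3 417 ± 43.8 and 477 ± 83.3 CPM and Sdha 267 ± 33.6 and 226 ± 30.3 CPM.

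Cholesterol synthesis (19 tested genes) and glycolysis and insulin action (29) had 0 genes past the threshold. Insig1, which holds back sterol synthesis, had 165 ± 34.2 and 116 ± 3.34 CPM (SD, n = 3), Fdft1 46.3 ± 3.88 and 34.9 ± 9.86 CPM and Msmo1 30.6 ± 4.53 and 24 ± 3.33 CPM. Pik3r1, a regulatory subunit of PI3-kinase, had 185 ± 27 and 240 ± 38.1 CPM, the pyruvate dehydrogenase kinase gene Pdk2 75 ± 4.18 and 94.5 ± 9.94 CPM, Eno1 199 ± 3.51 and 241 ± 52.2 CPM and Pgk1 113 ± 9.13 and 132 ± 12.4 CPM.

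Of 15 tested clock genes 0 passed, with 1 higher (Usp2) and 1 lower (Dbp) adjusted over the list alone. Usp2, a rhythmic deubiquitinase, had 33.9 ± 15.4 and 58.1 ± 16.3 CPM (SD, n = 3), and the clock output factor Dbp 161 ± 32.4 and 110 ± 17.3 CPM. Rora had 24.1 ± 3.37 and 31.6 ± 9.77 CPM and Per1 76.8 ± 24.4 and 95.5 ± 21.5 CPM. In the unfolded protein response 0 of 22 genes passed: Manf had 31.4 ± 4.6 and 51 ± 12.4 CPM, Asns 49 ± 5.53 and 69.5 ± 18.1 CPM, Hspa5 227 ± 31.6 and 262 ± 22.4 CPM and Xbp1 172 ± 32.1 and 150 ± 8.34 CPM. Heat shock and cold-inducible RNA binding genes also had 0 of 18 past the threshold. The chaperone gene Hspa8 had 592 ± 24.6 and 756 ± 100 CPM, the cold-inducible Cirbp 85 ± 15.7 and 106 ± 15.4 CPM, Hsp90aa1 189 ± 15.3 and 221 ± 17 CPM and Dnajb4 65.5 ± 9.33 and 52.3 ± 6.64 CPM.

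Interferon response genes had a median log2 fold change of -0.18 over 21 genes (camera adjusted p = 0.0729), with 0 past the threshold. Ifi27l2a had 4016 ± 472 and 2861 ± 698 CPM (SD, n = 3), Bst2 68.3 ± 10.4 and 49.1 ± 7.07 CPM and the immunoproteasome gene Psmb9 46 ± 3.88 and 32.2 ± 6.41 CPM. Of 32 genes of the extracellular matrix 0 passed. The collagen cross-linking enzyme genes Lox and Loxl1 had 31.2 ± 8.98 and 58 ± 18.4 CPM, and 62 ± 3.61 and 86.4 ± 12.7 CPM, Timp3 had 279 ± 14.7 and 223 ± 31.9 CPM and Col4a2 310 ± 33.7 and 383 ± 123 CPM.

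Median log2 fold changes were 0.02 for 19 fibroblast and precursor genes, 0.00237 for 21 macrophage genes, -0.04 for 18 endothelial genes and -0.08 for 14 pericyte and smooth muscle genes, with 0 genes of these lists past the threshold. Among the first, Pdgfra had 21 ± 6.77 and 28.7 ± 3.6 CPM (SD, n = 3), Gsn 8368 ± 726 and 7076 ± 592 CPM, Mfap5 77.1 ± 25.8 and 96.4 ± 41 CPM and Sfrp1 29.1 ± 2.64 and 34.6 ± 14.4 CPM. Of the macrophage genes Trem2 had 19.1 ± 4.07 and 11.2 ± 3.07 CPM, Ccr2 22.3 ± 5.09 and 32.2 ± 15.5 CPM, Retnla 905 ± 237 and 754 ± 133 CPM and Mrc1 109 ± 15.9 and 125 ± 30.1 CPM. Of the endothelial genes Cldn5 had 106 ± 5.52 and 78.3 ± 16.6 CPM, Egfl7 166 ± 22.2 and 131 ± 38.6 CPM, Cdh5 248 ± 36.7 and 207 ± 37.2 CPM and the lymphatic gene Lyve1 25.6 ± 6.05 and 33.4 ± 19.2 CPM. Mylk had 242 ± 69.7 and 161 ± 17.3 CPM, Rgs5 261 ± 57 and 191 ± 23.2 CPM, Kcnj8 59.9 ± 4.45 and 41.7 ± 6 CPM and Acta2 121 ± 41.1 and 172 ± 27.8 CPM.

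The dendritic cell list had a median log2 fold change of -0.15 over 7 genes, with 0 past the threshold. H2-Ab1 had 489 ± 42.2 and 381 ± 85 CPM (SD, n = 3), Irf8 25.1 ± 3.54 and 20.7 ± 4.03 CPM, H2-Eb1 301 ± 14.9 and 268 ± 24.6 CPM and Batf3 11 ± 3.53 and 8.32 ± 2.42 CPM. The B and plasma cell list had a median of -1.09 over 5 genes, with 0 past the threshold and 2 lower adjusted over the list alone. These were the immunoglobulin genes Igkc (223 ± 164 and 101 ± 10.3 CPM) and Jchain (57.6 ± 51.5 and 18.2 ± 8.01 CPM), both with the highest value in ctrl 5. Iglc2 had 24.1 ± 28.2 and 10.6 ± 3.69 CPM, with a log2 fold change of 0.40 without ctrl 5, and Ebf1 144 ± 17.9 and 121 ± 7.9 CPM. In the erythrocyte list 1 of 7 genes rose, Car2, a carbonic anhydrase also used by epithelia, from 5.05 ± 1.44 to 17.4 ± 4 CPM (edgeR adjusted p = 0.0273); it lost the call without each mouse but cold 7. Bpgm had 16.2 ± 2.18 and 19 ± 0.457 CPM, Hbb-bt 597 ± 186 and 538 ± 163 CPM and Hba-a1 91.4 ± 29.4 and 86.5 ± 30.8 CPM.

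Among 11 mesothelial markers the keratin genes Krt8 (4.46 ± 2.99 to 35.8 ± 12 CPM) and Krt18 (5.19 ± 1.91 to 31.2 ± 11.6 CPM) rose. The other 9 did not pass, among them Gpm6a with 35.3 ± 9.89 and 21.2 ± 12.7 CPM and Upk3b with 67.5 ± 32.9 and 37.4 ± 28.6 CPM, so the list's median was -0.16 and its mean 0.25.

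The list of epididymal epithelium markers, fixed for the neighbouring organ, summed to 19.2 ± 6.51 CPM in controls and 253 ± 213 CPM in the cold (SD, n = 3, exact permutation p = 0.1, the smallest possible). Cold 7 had 222 reads of Crisp1 and 91 of Spink8, secreted proteins of the epididymis, while cold 12 had 0 of both, cold 16 had 2 and 0, and no control library had more than 1. Without Lcn2 the list stood at 455 CPM in cold 7, 3.35 in cold 12, 8.94 in cold 16 and 5.23 to 7.06 in the controls. Male germ cell markers summed to 73.4 ± 9.1 and 214 ± 68.2 CPM (exact permutation p = 0.1). In cold 16, Sycp3 with 68 reads and Odf2 with 24 made up most of the 106 reads of this list, and both were also read in every control library (30, 58 and 43, and 32, 30 and 23). The sperm protamine gene Prm1 had 19 reads in cold 7, 51 in cold 12, 1 in cold 16 and 1, 6 and 1 in the controls, and Tnp1 had 16, 29, 1 and 0, 4 and 1. The genes of these lists named here were chosen after their values were seen. T and NK cell markers summed to 94.6 ± 10.9 and 74.5 ± 7.19 CPM and Schwann cell and neuron markers to 236 ± 25.5 and 203 ± 11.9 CPM, with all cold mice below all control mice in both (exact permutation p = 0.1, the smallest possible). Skeletal muscle markers summed to 83.6 ± 21.6 and 76.2 ± 9.29 CPM (exact permutation p = 0.6), neutrophil and mast cell markers to 74 ± 12.7 and 73.6 ± 25.9 CPM (exact permutation p = 1) and proliferation markers to 144 ± 13.8 and 140 ± 28.7 CPM (exact permutation p = 1).

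**Figure D3:**
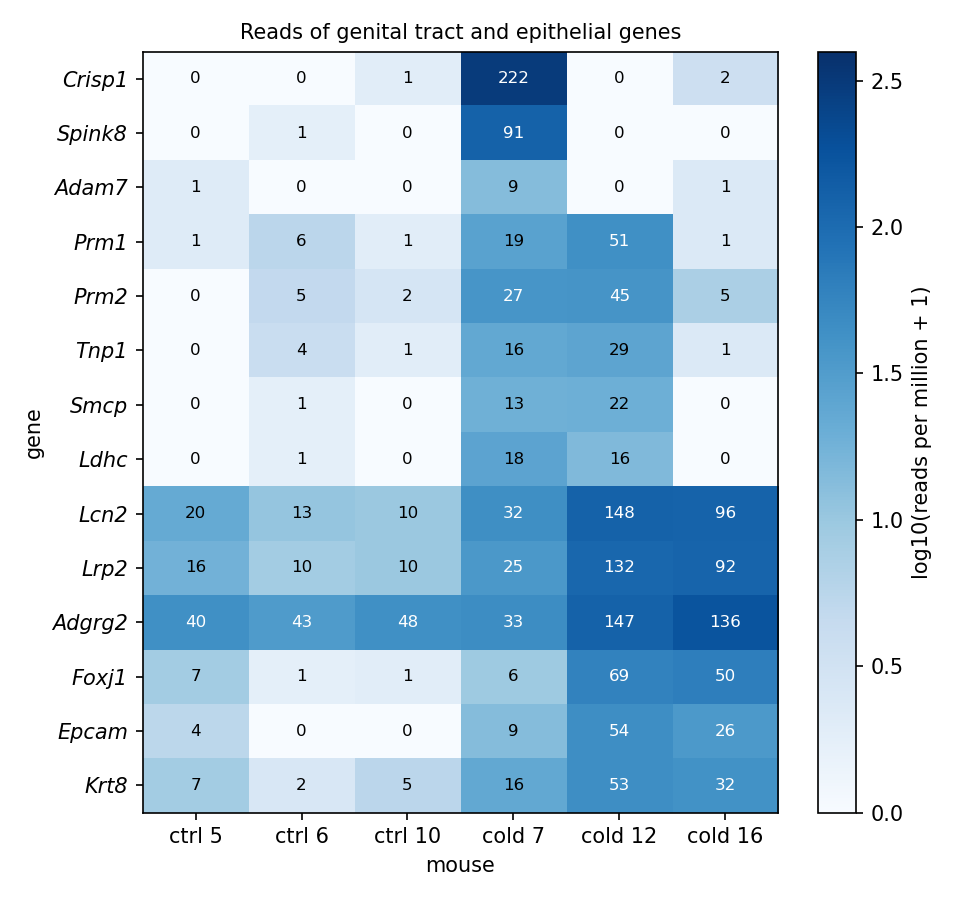
Reads of epididymal (Crisp1, Spink8, Adam7), sperm (Prm1, Prm2, Tnp1, Smcp, Ldhc) and epithelial genes in each mouse; the number in a cell is the read count and its colour is log10 of CPM plus 1. Crisp1 and Spink8 are abundant in cold 7 alone, the sperm genes in cold 7 and cold 12, and Epcam, Krt8 and Lcn2 are higher in all cold mice than in any control mouse on the CPM scale.

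At the level of transcripts, 47 of 12325 passed the threshold, 40 higher and 7 lower, from 44 genes. Of them 34 were protein-coding, 4 lincRNA, 3 targets of nonsense-mediated decay and 2 retained introns. The gene itself had passed for 46, and 21 of the 64 called genes had no called transcript. The exception was Wdr61-202 (ENSMUST00000118771.7, chromosome 9, 54714735 to 54734482) of Wdr61, a subunit of the PAF1 and SKI complexes. It rose by 3.11 ± 0.50 (SE, log2 scale), from 4.39 ± 2.57 to 35.5 ± 23.9 CPM (SD, n = 3, edgeR adjusted p = 0.00254), with 6, 2 and 6 reads in the controls and 8, 44 and 46 in cold 7, cold 12 and cold 16. Its 3' end extends beyond those of the other tested Wdr61 transcripts, and 1581 of its 3372 exonic bases coincide with exons of Dnaja4 on the opposite strand. Dnaja4, named here for this overlap after its values were seen, was itself higher in the cold (8.91 ± 3.29 and 30.4 ± 4.1 CPM). It may share reads with Wdr61-202, as the use of strand is not known.

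The next transcripts by p whose gene did not pass were Esr1-204 of the estrogen receptor α gene, with 26.3 ± 6.1 and 52.6 ± 17.2 CPM (edgeR adjusted p = 0.0743), and Ephx2-202, Arl4c-202, Ap1s2-203, Clmp-201, Slc35g1-201 and Srpx2-201, up to an adjusted p of 0.106 (edgeR). The downward transcripts with the smallest p were Asah2-209, Mknk2-205, C2-201, Cfd-201, A530020G20Rik-202, Mrps6-203 and C6-204 (edgeR adjusted p 0.112 to 0.188). The count of called transcripts was 162 without cold 7, 71 without ctrl 5, 71 without cold 16, 26 without cold 12 and 487 without both cold 7 and cold 12.

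Transcript usage was tested in 2624 genes with at least 2 transcripts past the filter. Here 0 genes passed by edgeR's diffSpliceDGE, 24 had an unadjusted p under 0.05, and 0 passed by limma's diffSplice. The smallest p belonged to Wdr61 (edgeR adjusted p = 0.0768), in which Wdr61-202 took 9.03% ± 5.45 of the gene's reads in controls and 38.6% ± 20.6 in the cold (SD, n = 3), and Wdr61-201 took 52% ± 4.75 and 36.9% ± 9.87. It passed without cold 7 (edgeR adjusted p = 0.00158), by an F test per gene (0.0276) and with no filter (0.00138). It did not pass without ctrl 5 (0.376), ctrl 6 (1 after rounding), ctrl 10 (0.747), cold 12 (0.39) or cold 16 (1 after rounding) by edgeR's adjusted p, nor by limma (0.697). Next came Acaa2, a mitochondrial thiolase, in which the short transcript Acaa2-202 took 8.17% ± 1.72 and 22.1% ± 10.4 (edgeR adjusted p = 0.9). In Sec14l1, the share of Sec14l1-201 was 15.6% ± 4.77 and 29.2% ± 4.85, and in Gyg that of Gyg-203 was 7.9% ± 3.7 and 16.9% ± 7.82. These 2 genes and the other 4 of the 8, Nnmt, Uqcrq, Higd1a and Oaz1, had an adjusted p of 1 after rounding (edgeR). Without both cold 7 and cold 12, leaving 1 cold mouse whose spread is assumed to be that of the controls, 41 genes passed.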

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

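No paired analysis was possible because the mouse numbers of the groups are not shared. The fit without cold 7 and cold 12 was chosen after seeing the data; it leaves 1 cold mouse, assumed to vary like the controls, and the causes of the differences below were not tested unless a reason is given.

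Called genes numbered 46 (DESeq2), 48 (limma-voom), 64 (DESeq2 size factors), 63 (no composition factor), 52 (10 reads in 3 libraries), 46 (X1 files) and 71 (no mitochondrially encoded genes), within 1.5 times of 64; 45 of the DESeq2 and 47 of the limma-voom calls were among the 64. The count was 371 with no filter, 38 with X2 files alone (fewer reads), 35 to 199 with each mouse left out, and 141 without cold 7 and cold 12, where 42 of the 64 remained. Called transcripts numbered 260 with no filter, 30 with X1 and 26 with X2 files alone, 26 to 162 with each mouse left out and 487 without cold 7 and cold 12. Genes with changed usage numbered 1 by an F test per gene, 1 with no filter, 0 to 1 with each mouse left out and 41 without cold 7 and cold 12. Lists past the threshold numbered 0 with an estimated correlation, 0 by fry, 5 with no filter, 6 with X1 files, 1 with X2 files, 2 to 8 with each mouse left out and 5 without cold 7 and cold 12. The median r between the files of a mouse was 0.946, and 0.963 over all genes with a read.

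Of 30 named genes past the threshold, 10 lost the call by DESeq2 (among them Calml3, Epcam, Ccdc153, Dcdc2a, Col6a6, Gadd45g, Dhrs3, Cd200, Car2), 7 by limma-voom (Mt3, Dcdc2a, Col6a6, Dhrs3, Cd200, Ckb, Car2), 1 with 10 reads in 3 libraries, 3 with X1 and 5 with X2 files, besides those untested there. Leaving out cold 12 ended 13 of these calls, ctrl 6 ended 12, ctrl 10 ended 8, cold 16 ended 7, ctrl 5 ended 4 and cold 7 ended 0. None of the 30 changed sign. Of the named genes not past the threshold, 25 passed in some alternative, 17 of them with no filter and 12 without cold 7; Cfd and Lep did so in 5 each (smallest adjusted p 0.0123 and 0.000659). Genes not past the threshold that changed sign had these log2 fold changes. Fasn had -0.0555 by limma-voom, and with each mouse left out -0.52 to 0.305 (-0.0827 without ctrl 10). With each mouse left out Mfap5 had -0.0141 to 0.568, Mrc1 -0.0034 to 0.367, Iglc2 -1.64 to 0.398, Hbb-bt -0.418 to 0.142 and Hba-a1 -0.317 to 0.209. With X2 files Acads had 0.0476 and Gpm6a 0.179, and with X1 files Pgk1 had -0.0215. Without cold 7 and cold 12, Eno1 had -0.12, Mfap5 -0.276, Lyve1 -1.12, Hba-a1 0.142 and Lipe 0.0138, and the ribosomal list turned downward (camera adjusted p = 0.923).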

Other observations

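The tests on the post hoc lists were chosen after the gene test was seen, with their bounds set before the values of their members; those on the epididymal duct, the fat cell response, the lower genes and cold 16 were chosen after the results were seen. The counts over other splits were planned.

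Biology outside the fixed comparisons was sought in 3 lists written after the gene test, from which called genes were left out. The motile cilia list (26 genes with a read) summed to 79.2 ± 34.7 CPM in controls and 221 ± 68.4 CPM in the cold (SD, n = 3). The simple epithelium list (22 genes) summed to 33.5 ± 8.3 and 129 ± 26.2 CPM, and the efferent duct list (11 genes) to 64.6 ± 9.02 and 107 ± 19.3 CPM. In each list all cold mice were above all control mice (exact permutation p = 0.1, the smallest possible). Foxj1, a transcription factor of ciliated cells, was chosen after its values were seen. It had 7, 1 and 1 reads in the controls and 6, 69 and 50 in cold 7, cold 12 and cold 16. In cold 7 this was 8.27 CPM, against 7.47 CPM in ctrl 5, while the motile cilia list summed to 164 CPM in cold 7. Whether the germ cell transcripts of cold 7 and cold 12 add to the motile cilia sum was not tested.

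The pattern most in need of a second look is the rise of 53 genes, with Epcam, Cldn7, Krt8 and Krt18 among them. The 53 need not share 1 source. Over these genes, the median excess of cold 7 above the control mean was 0.384 of the mean excess of cold 12 and cold 16. The same ratio was 1.05 for Pnpla2 and 1.41 for Mgp. Thrsp was itself the gene at the median, so its 0.384 is no separate match. These genes were chosen here after their values were seen. For the epithelial genes, a candidate source is epithelium of the ducts that join the testis and epididymis, which lie against this fat pad. The 3 lists together were 2.58 times higher in the cold, over the bound of 1.5 set for it. The ratio was 3.86 for simple epithelium, 2.79 for motile cilia and 1.66 for the efferent duct, the only list named for these ducts. All 3 were written after these libraries had shown the rise of epithelial genes. Passing the bound is therefore no independent support for this source. Epithelium of the epididymal duct is argued against for cold 12, where the epididymal list without Lcn2 was 3.35 CPM, below the 5.23 to 7.06 CPM of the controls. In cold 16 it was 8.94 CPM, above all controls though far under the 455 CPM of cold 7, so a small share stays open there; the average of both was 6.15 CPM. A response of the fat cells themselves stays open, since no cold sample lacks the epithelial genes. Of the 53, 44 were lowest in cold 7, the cold library with the epididymal transcripts. Male germ cell transcripts were not confined to cold 7. Their list summed to 247 CPM in cold 7, 259 in cold 12 and 135 in cold 16, against 66.2 to 83.6 CPM in the controls. In cold 16 most of these reads were of Sycp3 and Odf2, which all controls also had. Where the germ cell transcripts came from was not tested. The sums of the 3 lists written after the gene test also varied without cold. The motile cilia list had 118 CPM in ctrl 5 against 52.3 in ctrl 6 and 67.1 in ctrl 10, and simple epithelium 42.7 against 31.4 and 26.5. The efferent duct list was lowest in ctrl 5, with 54.4 against 67.9 and 71.5 CPM. Adipocytes also express Lcn2, and the dissection is not described further.

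The fall of 11 genes was set against dilution of fat RNA by other tissue. Dilution would lower all adipocyte markers by about as much, at least by the log2 fold change of -0.67 of the least changed of the 11. The median of the mature adipocyte markers was -0.0763 with an interquartile range of 0.251. TMM normalization can scale out part of a dilution, but its factors lay between 0.975 and 1.025. Without TMM, the CPM of these markers summed to 90001 ± 3288 in controls and 86062 ± 3946 in the cold (SD). These values argue against dilution of adipocyte RNA. A loss of other cells of the fat pad would not show in these markers and was not tested. A response to cold, or to housing alone, stays open and was not tested.

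The higher values of the mitochondrially encoded mRNAs in the cold, of which 0 passed alone, may come in part from cold 16. This library had more reads on introns and mitochondrial tRNAs. The rise was not confined to it. Mitochondrially encoded genes of all types took 6.75% of gene reads in cold 7 and 6.45% in cold 12, against 5.76% to 6.1% in the controls. Without cold 16 the median was 0.17, between the bounds of 0.1 and 0.2, which were written after the results were seen. Without cold 16, 13 of 13 genes were still higher. These genes vary together (estimated correlation 0.584), so they do not count as 13 independent signs. How much is a cold effect and how much the make-up of cold 16 cannot be told apart for these genes.

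The 6 mice can be split in 10 ways, too few for a share under 0.05. The real split gave 64 genes where the highest other split gave 5, and 47 transcripts where it gave 3; each was matched by 1 split, the real one. For usage all 10 splits gave 0 genes. For the lists, 6 of the 10 splits gave at least the real 3. The highest gave 10, the split that puts ctrl 5, ctrl 10 and cold 7 against the rest. This may come from the preset correlation of 0.01, as 0 lists passed in the real split with an estimated correlation or by fry. A structure among the mice that the groups do not follow was not tested.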
